A study of Mus musculus with 17 samples.

How the data were processed

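RNA was sequenced from 17 mouse tumours labelled as neuroendocrine pituitary tumours, 9 with engineered alleles of Rb1 and Trp53 and 8 with those of Rb1, Trp53 and Crebbp. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo-dT beads and libraries were made with a NEBNext Ultra RNA kit. Per the submitters' processing notes, the tools named were bcl2fastq 1.8.2, TopHat2 2.0.12 and HTSeq 0.6.1 and the genome build was mm9. The annotation, the strand setting of the counting and any read filter are not given in the sources used here, so an antisense or overlapping gene cannot be told from its partner. The authors deposited 1 table of raw counts per tumour, with 23284 gene symbols and 5 summary rows that name no gene. The 5 rows were left out of library sizes and tests. Reads assigned to no feature made up 11.7% to 21.7%, reads that did not align uniquely 8.20% to 18.5% and ambiguous reads 0.56% to 0.843% of each table, and genes held 64.5% to 78.3%. The total on genes was 8328297 to 28140755 per library, so a gene at 1 CPM rests on a handful of reads in the shallower libraries.

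The 10 most abundant genes took 7.62% to 32.5% of the gene counts. No 2 tables of the same genotype held the same library. Over 64 pairs within a genotype, the chi-square per degree of freedom was 8.30 or higher, over genes with a summed count of at least 10. Pairs across genotypes were not compared in this way.

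Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype as group, which left 14338 genes over all 17 libraries, libraries were scaled by TMM, and the genotype was tested with the robust quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg, and adjusted p-values under 0.05 count as changed. Log2 fold changes are Rb1/Trp53/Crebbp over Rb1/Trp53, and the SE is the absolute log2 fold change divided by the square root of F. CPM values are counts scaled to a common total on genes (edgeR), and log2 CPM used a prior count of 2. The design has 1 contrast and no covariate, and no batch, sex or animal is given in the labels.

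Gene lists, 39 in number with 1229 entries, were fixed before the data were examined, as were the main test, the other settings to be tried and the rule for named genes. Of the entries, 1224 matched a symbol of the tables, 19 of them through a synonym in the RefSeq table for GRCm38, which was used for names and for the order of genes along chromosomes and not for positions. Lists with at least 5 tested genes, 36 of them, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry and with an exact two-sided permutation test of the mean log2 CPM per tumour. With an estimated correlation 0 lists passed camera in each fit; 4 of 36 had an unadjusted p under 0.05 over all 17 libraries, 1 in the Pomc-high and 5 in the Calca-high ones. The named genes are Crebbp, Ep300, Rb1 and Trp53, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 5 CPM and a group median outside the other group's interquartile range, leaving out unnamed gene models, sex-linked genes and haemoglobins. They also include up to 4 members per list with the smallest adjusted p, and 12 genes that describe the tumour type. Tg, Nkx2-1, Ret, Tbx19, Insm1, Cend1 and the lung genes were named after their values had been seen. Principal components were computed on log2 CPM of the 500 most variable tested genes, and group differences in score were tested with scipy 1.17.1 by exact two-sided permutation. That test doubles the smaller tail, while the test of the lists counts differences at least as large in either direction, so the smallest p of the list test is lower. Figures were drawn with matplotlib 3.10.9.

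After the data had been seen, libraries with more Pomc than Calca were called Pomc-high (10) and the others Calca-high (7). The set was added as a term of the fit, the genotype was tested within each set (14010 and 14797 genes), and an interaction of genotype and set was tested. The overlap of the gene tables of the 2 sets was tested, and the levels of thyroid, lung and anterior lobe genes were compared between the sets.

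The other settings were DESeq2 size factors, upper-quartile normalization, no low-count filter, a filter of at least 1 CPM in at least 8 libraries, DESeq2 1.42.0, limma-voom with and without quality weights (limma 3.58.1), the tumour number as a block, covariates for Y-linked genes and for 3 lists of other cell types, 1 surrogate variable (sva 3.50.0), and each tumour left out in turn. The fit was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 genes changed. Over all 17 libraries (14338 genes) it recovered 67% of genes changed 2-fold and 83% of those changed 4-fold, with 2 false calls. In the Pomc-high libraries (14010 genes) it recovered 74% and 92% with 6 false calls, and in the Calca-high libraries (14797 genes) 64% and 89% with 9 false calls.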

Results

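Gene expression was measured by RNA sequencing in 17 mouse tumours, each given in the labels as a neuroendocrine tumour of the pituitary. The engineered alleles were Rb1 and Trp53 in 9 tumours and Rb1, Trp53 and Crebbp in 8 tumours. Rb1 encodes the retinoblastoma protein, Trp53 encodes p53, and Crebbp encodes a histone acetyltransferase that acts as a coactivator of transcription. The total count on genes ranged from 8328297 to 28140755 per tumour, with a median of 13456360. Nothing in the labels says that the tumours came from separate mice, so the p-values below measure only the spread between these samples. The study asked which genes Crebbp regulates in primary pituitary tumours, and the labels give a single contrast for this, the 8 tumours with the Crebbp allele against the 9 without.

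The 17 libraries fell into 2 sets by the hormone gene that dominated them. In 10 libraries Pomc, the precursor of ACTH and the melanocyte-stimulating hormones, stood between 106000 and 278100 CPM (counts scaled to a common library total), and in the other 7 it stood between 4.19 and 73.1 CPM. Those 7 libraries instead had Calca, the calcitonin gene, at 40310 to 165400 CPM, against 4.24 to 242 CPM in the 10 others. Tbx19 and Pax7, transcription factors of Pomc-producing pituitary cells, stood at 275 to 440 and 141 to 294 CPM in the 10 libraries, and at 0.36 CPM or below in the 7. Nkx2-1, the receptor gene Ret and the epithelial cadherin gene Cdh1 went the other way, with 220 to 332, 137 to 418 and 61.8 to 297 CPM in the 7 libraries. Neuroendocrine genes were present in both sets: Chga stood at 3677 CPM or above and Syp at 267 CPM or above in all 17 libraries. The 7 Calca-high libraries were 3 of the Rb1/Trp53 group (T1, T3 and T4) and 4 of the Rb1/Trp53/Crebbp group (T1 to T4), and the 10 Pomc-high libraries were 6 and 4. The sets were defined from these counts and are not groups of the study.

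**Figure D1:**
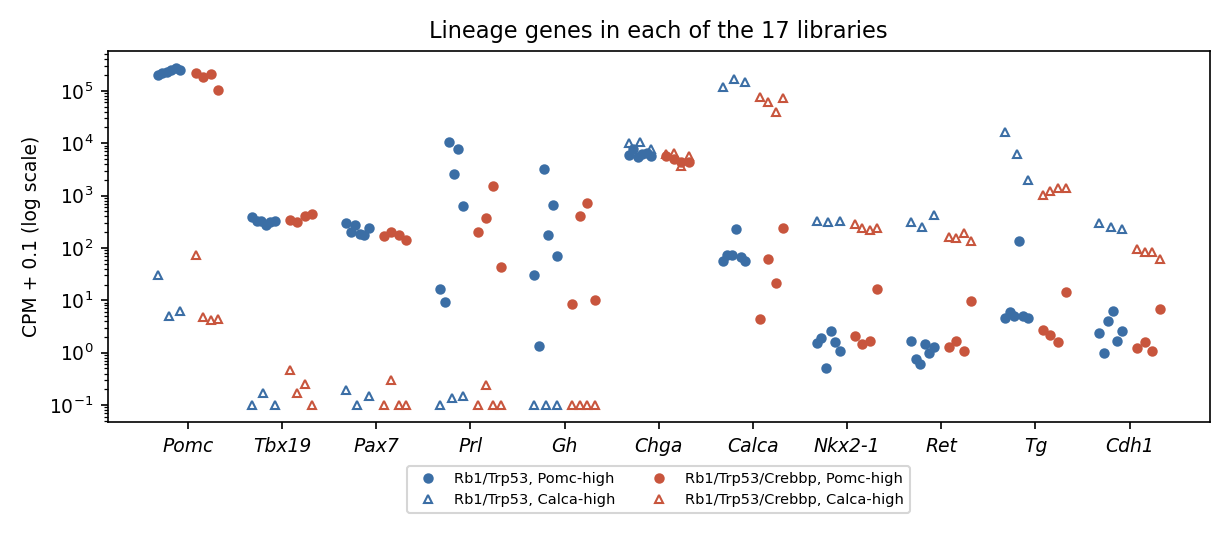
CPM (plus 0.1, log scale) of 11 lineage genes, 1 point per library, with Rb1/Trp53 in blue, Rb1/Trp53/Crebbp in red, filled circles for the 10 Pomc-high and open triangles for the 7 Calca-high libraries. Pomc was at 106000 CPM or above in the circles and at 73.1 CPM or below in the triangles, and both genotypes occurred in both sets.

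Over all 17 libraries Crebbp itself had nearly the same whole-gene count in both genotypes, at 34.7 to 114 CPM in the 9 libraries labelled Rb1/Trp53 and 41.0 to 109 CPM in the 8 labelled Rb1/Trp53/Crebbp (log2 fold change -0.01 ± 0.20 SE, adjusted p = 0.978, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The counts cover whole genes, so they do not test whether an exon was deleted and do not check the labels. Ep300, the close relative of Crebbp, had a log2 fold change of 0.44 ± 0.14 (adjusted p = 0.0731). Rb1 (0.35 ± 0.19, adjusted p = 0.293) and Trp53 (-0.53 ± 0.15, adjusted p = 0.0604) did not pass the threshold either. The sign of the Crebbp value turned in several alternative fits and differed between the sets: its count was higher in the Rb1/Trp53/Crebbp group in the 7 Calca-high libraries (0.60 ± 0.12, adjusted p = 0.00723), and in the 10 Pomc-high ones its log2 fold change was -0.47 ± 0.23 (adjusted p = 0.239).

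Over all 17 libraries Adcyap1r1, the receptor of the neuropeptide PACAP, rose in the Rb1/Trp53/Crebbp tumours, from 1.19 ± 0.58 CPM (SD, n = 9) to 20.7 ± 28.4 CPM (SD, n = 8), with a log2 fold change of 3.86 ± 0.75 SE (adjusted p = 0.0112). The GABA-B receptor subunit gene Gabbr2 (3.12 ± 0.58), the membrane glycoprotein gene Gpm6b (2.67 ± 0.53), the glutamate transporter gene Slc1a2 (3.54 ± 0.91), the neuronal calcium sensor gene Vsnl1 (4.54 ± 1.001) and Stmn2, a regulator of neuronal microtubules (2.25 ± 0.60), also rose. Cwc22, a splicing factor gene, stood apart with 30.8 ± 2.79 CPM in the Rb1/Trp53 libraries and 660 ± 88.5 CPM in the others (4.24 ± 0.10, adjusted p = 2.34e-14), with no overlap between the genotypes. Its reads may be shared with near-identical copies, so its value is uncertain. The cytokine gene Il1f9 rose by 2.50 ± 0.21 (adjusted p = 3.57e-06). The thyroid hormone deiodinase gene Dio1 (-1.95 ± 0.34), the interferon-induced gene Ifi27l2a (-1.83 ± 0.25), the protein C receptor gene Procr (-1.81 ± 0.29), Gdpd3 (-3.40 ± 0.66) and Fabp4, a lipid carrier of fat cells and endothelium (-2.27 ± 0.62), fell. Of these genes, Stmn2, Cwc22, Il1f9, Dio1, Ifi27l2a and Procr also passed the threshold in the same direction within each set. For Adcyap1r1, Gabbr2, Gpm6b and Slc1a2 the fit over all 17 libraries does not show which set carries the rise. The SD of Adcyap1r1 exceeded its mean in the 8 Rb1/Trp53/Crebbp libraries, so its level was uneven among them.

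In all, 554 of 14338 tested genes changed at an adjusted p under 0.05, 260 higher and 294 lower in the Rb1/Trp53/Crebbp tumours, and 182 of them changed at least 2-fold (85 higher, 97 lower). Unadjusted p-values under 0.05 were found for 3126 genes. Of the 24 most changed genes with a mean of at least 5 CPM, 12 in each direction, the remaining ones were Rab11fip4, Jph3, Onecut2 and Thbs4 (log2 fold changes of 2.67, 2.47, 2.43 and 2.33), and Cpa5, Reep6, Fkbp10, Enpep, Naip2, Gstm2 and Entpd3 (between -2.06 and -1.64). Vsnl1 reached a mean of 5 CPM through a single library, T8 of the Rb1/Trp53/Crebbp group, at 80.2 CPM, and its log2 fold change without that library was 2.10 (adjusted p = 0.0234). Slc1a2 was no longer past the threshold without that library (1.28, adjusted p = 0.102), nor was Stmn2 (1.38, adjusted p = 0.0888). Of 66 called genes named by the rule, 35 kept their call in each of the 17 fits that left out 1 tumour, among them Cwc22, Il1f9, Adcyap1r1, Gabbr2, Gpm6b, Rab11fip4, Onecut2, Dio1, Ifi27l2a, Procr and Gdpd3, while others lost it in 10 or more, among them Rfng, Fabp4, Stmn2, Neurod4, Kcnq3, Jph3, Slc1a2, Cdh6, Cd68, Sdf2l1, Creld2 and Ccna2, and Notch3 lost it in 4. The count of 554 fell to 313 without Rb1/Trp53 T7, 327 without T8, and 313, 329, 293 and 284 without Rb1/Trp53/Crebbp T1, T2, T3 and T4, and it was 1031 without Rb1/Trp53/Crebbp T5. With the set (Pomc-high or Calca-high) as a term of the fit, a choice made after the sets had been seen, 2575 genes changed, 1178 higher and 1397 lower, among them 551 of the 554.

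**Figure D2:**
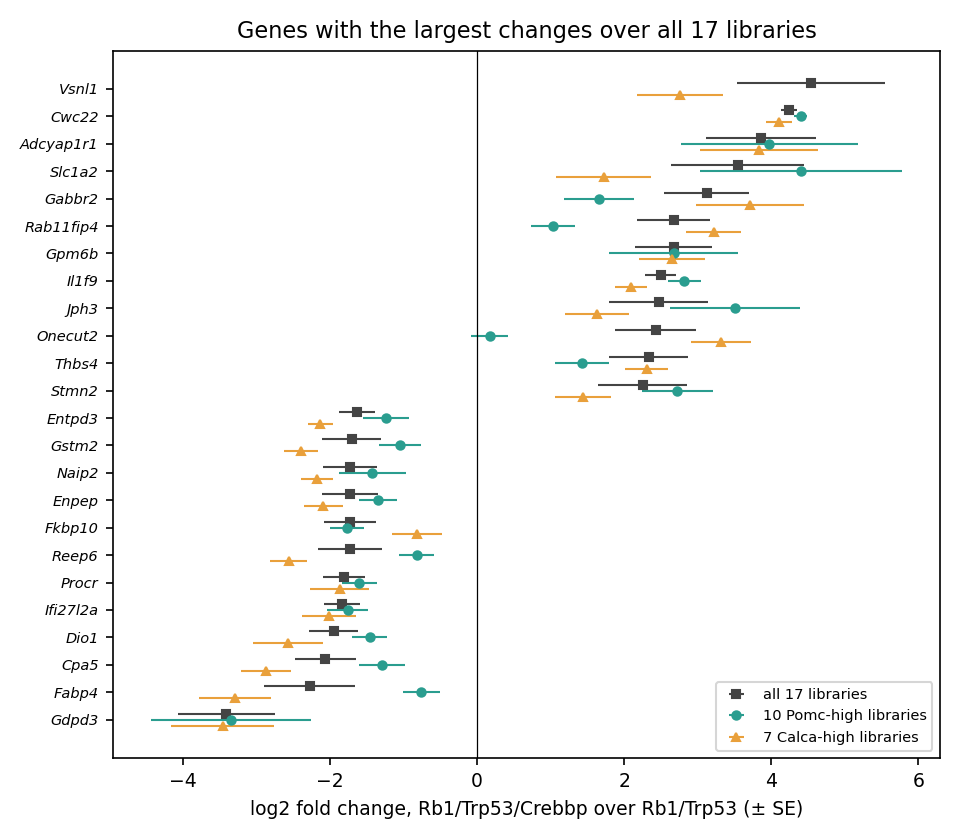
Log2 fold change (Rb1/Trp53/Crebbp over Rb1/Trp53, ± SE from the edgeR fit) of the 24 most changed genes over all 17 libraries (squares), in the 10 Pomc-high (circles) and in the 7 Calca-high libraries (triangles). Cwc22 lay at 4.24, 4.40 and 4.10 in the 3 fits, and Vsnl1 was not tested in the Pomc-high libraries because of its low counts.

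Over all 17 libraries 2 of 36 fixed gene lists passed both the camera test and an exact permutation test of the list's mean per tumour. They were neuronal differentiation (higher in the Rb1/Trp53/Crebbp tumours) and the unfolded protein response (lower), and neither passed camera with an estimated correlation. Of 23 measured genes of neuronal differentiation, Onecut2 (2.43 ± 0.55), Stmn2 and the neuronal RNA-binding gene Elavl3 (1.68 ± 0.39) rose, Neurod4 fell (-0.65 ± 0.18) and 19 did not pass. Adjusted over the list alone, 5 rose and 2 fell. The list's median log2 fold change was 0.42, with an adjusted p of 0.0028 (camera), an adjusted p = 0.161 with an estimated correlation and an adjusted p = 0.00296 by exact two-sided permutation of all 24310 regroupings. Of 14 posterior lobe pituicyte and astroglia genes, 2 rose, and 4 rose and 1 fell when adjusted over the list alone (median 0.71, adjusted p = 0.0541 by camera and 0.815 with an estimated correlation). Of 12 genes of neurons and oligodendrocytes, 0 passed, and 1 rose and 1 fell when adjusted over the list alone (median 0.14). Of 24 measured genes of the unfolded protein response, 5 fell, among them the chaperone gene Dnajb9 (-0.66 ± 0.15), the ubiquitin ligase gene Syvn1 (-0.35 ± 0.08), Creld2 (-0.55 ± 0.13) and Sdf2l1 (-0.62 ± 0.16), none rose and 19 did not pass. Adjusted over the list alone, 11 fell. The median was -0.28, with an adjusted p of 2.52e-06 (camera), an adjusted p = 0.161 with an estimated correlation and an adjusted p = 0.0207 by exact permutation.

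The other 8 lists past the camera threshold did not pass the exact permutation test over all 17 libraries. With the set as a term, some passed exact permutation: cell adhesion, Notch and endothelial genes (adjusted p = 0.00392 each), cell cycle (0.037) and macrophages (0.0416). Ion channels (0.192), chromatin remodelling (0.271) and ribosomal proteins (0.203) did not pass it. That term was chosen after the sets had been seen, and 0 lists passed camera with an estimated correlation there. Of 58 genes of the cell cycle and E2F targets, 6 rose, among them Bub1 (0.97 ± 0.22), Ccna2 (0.68 ± 0.17) and Mcm6 (0.60 ± 0.15), none fell, and 27 rose when adjusted over the list alone (median 0.55, adjusted p = 0.606 with an estimated correlation). Of 45 cell adhesion molecules, Nlgn1 (1.804 ± 0.24), Nlgn3 (1.25 ± 0.29), Cntn1 (2.22 ± 0.53) and Cdh6 (1.67 ± 0.43) rose, and 7 rose when adjusted over the list alone (median 0.57, adjusted p = 0.606 with an estimated correlation). Of 55 ion channel genes, 4 rose, among them the sodium channel genes Scn9a (2.02 ± 0.30) and Scn1a (1.55 ± 0.33) and the potassium channel gene Kcnq3 (1.37 ± 0.37), also when adjusted over the list alone (4 genes; median 0.15, adjusted p = 0.606 with an estimated correlation). Of 26 Notch pathway genes, Notch4 (-0.58 ± 0.12), Mfng (-0.80 ± 0.17), Notch3 (-0.75 ± 0.18) and Rfng (-0.31 ± 0.08) fell, and 5 fell when adjusted over the list alone (median -0.21, adjusted p = 0.198 with an estimated correlation). Of 21 endothelial genes, Ptprb (-1.11 ± 0.20), Icam2 (-1.46 ± 0.28), Kdr (-1.08 ± 0.23) and Emcn (-0.91 ± 0.20) fell, and 11 fell when adjusted over the list alone (median -0.67, adjusted p = 0.235 with an estimated correlation). Of 23 macrophage genes, Cd68 fell (-1.21 ± 0.31), as it did when adjusted over the list alone (1 gene; median -0.76, adjusted p = 0.606 with an estimated correlation). Of 32 genes of chromatin methylation and remodelling (median 0.22), 0 passed on its own with edgeR, 2 had an unadjusted p under 0.05, and 1 passed with DESeq2 and 0 with limma-voom. Of 46 ribosomal protein genes (median -0.26), 0 passed with edgeR, 3 had an unadjusted p under 0.05, and 0 passed with DESeq2 or limma-voom. Adjusted over the list alone the counts were also 0, and both lists had an adjusted p = 0.815 with an estimated correlation. Random regroupings of the 17 tumours gave 10 or more lists past the camera threshold in 77 of 100 splits, the real one included.

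Of 40 neuroendocrine and secretory granule genes, the granin gene Chga (-0.67 ± 0.16, adjusted p = 0.0261) and Slc18a1 (-1.12 ± 0.29) fell, Ncam1 (0.43 ± 0.10, adjusted p = 0.0298) and Sytl5 (1.22 ± 0.33) rose, and 36 did not pass. Adjusted over the list alone, 2 rose and 3 fell (median -0.05, adjusted p = 0.815 with an estimated correlation). Of 20 melanotroph and corticotroph genes, the prohormone convertase gene Pcsk2 (-1.17 ± 0.20, adjusted p = 0.00491) and Pam, which amidates peptide hormones (-0.84 ± 0.10, adjusted p = 4.05e-04), fell and 18 did not pass, also when adjusted over the list alone (median -0.30, adjusted p = 0.815 with an estimated correlation). Of 18 acetyltransferase genes, 0 passed with edgeR, over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and 1 passed with DESeq2 and 0 with limma-voom. Of 51 genes of epithelial adhesion and tight junctions, Tjp3 fell (-1.11 ± 0.22, adjusted p = 0.0124), as it did when adjusted over the list alone (1 gene). With the set as a term 13 fell and 2 rose (adjusted p = 0.00392 by exact permutation, 0.469 by camera with an estimated correlation). Within the Pomc-high libraries 6 of 47 fell and 0 rose (adjusted p = 0.837 by camera with an estimated correlation). Over all 17 libraries Cdh1 had a log2 fold change of -1.31 ± 1.27 (adjusted p = 0.588), but 3.16 (adjusted p = 0.041) with limma-voom and quality weights.

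**Figure D3:**
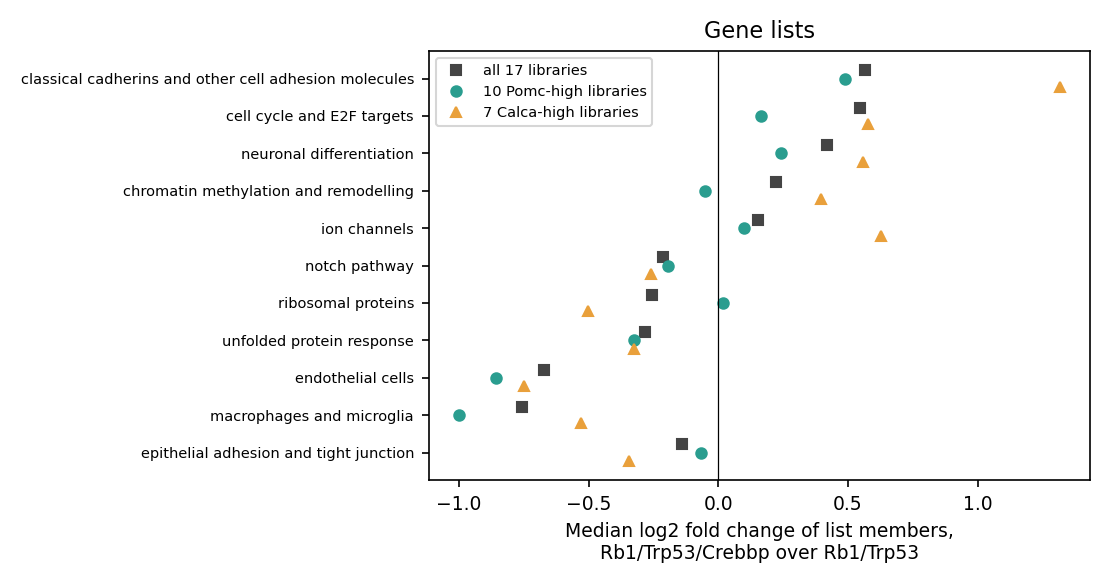
Median log2 fold change of the members of 11 fixed gene lists, Rb1/Trp53/Crebbp over Rb1/Trp53, over all 17 libraries (squares), in the 10 Pomc-high (circles) and in the 7 Calca-high libraries (triangles). The unfolded protein response lay at -0.28, -0.32 and -0.33 and neuronal differentiation at 0.42, 0.24 and 0.56.

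Variation among the tumours followed the 2 sets on the first principal component, and the genotypes lay apart on the second. The first principal component of the 500 most variable genes held 87.9% of the variance and placed the 10 Pomc-high libraries between 34.0 and 51.9 and the 7 Calca-high ones between -75.0 and -61.4. Over all 17 libraries its mean did not differ between genotypes beyond a spread set by the 2 sets (-8.77 ± 59.4 SD, n = 8, against 7.79 ± 60.2 SD, n = 9, exact two-sided permutation p = 0.746). Within the Calca-high libraries it lay between -75.0 and -69.1 in Rb1/Trp53 and between -65.5 and -61.4 in Rb1/Trp53/Crebbp tumours (exact two-sided permutation p = 0.0571, the smallest possible), and within the Pomc-high ones the exact permutation p was 0.771. The second component held 3.28% of the variance and its mean was -9.03 ± 7.32 (SD, n = 8) in Rb1/Trp53/Crebbp and 8.02 ± 7.43 (SD, n = 9) in Rb1/Trp53 tumours, with p = 8.23e-05, the smallest this exact two-sided permutation test, which doubles the smaller tail, can give. Within the sets the same exact permutation test of the second component gave p = 0.00952 for the 10 Pomc-high and p = 0.0571 for the 7 Calca-high libraries, again the smallest possible in each. Scores on it ran from -18.6 to 22.7 in the Calca-high libraries. In the Pomc-high ones they ran from -1.68 to 7.84, apart from Rb1/Trp53/Crebbp T8 at -15.5. Other features went with the genotype in the Calca-high libraries, so this component cannot be tied to the genotype alone.

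**Figure D4:**
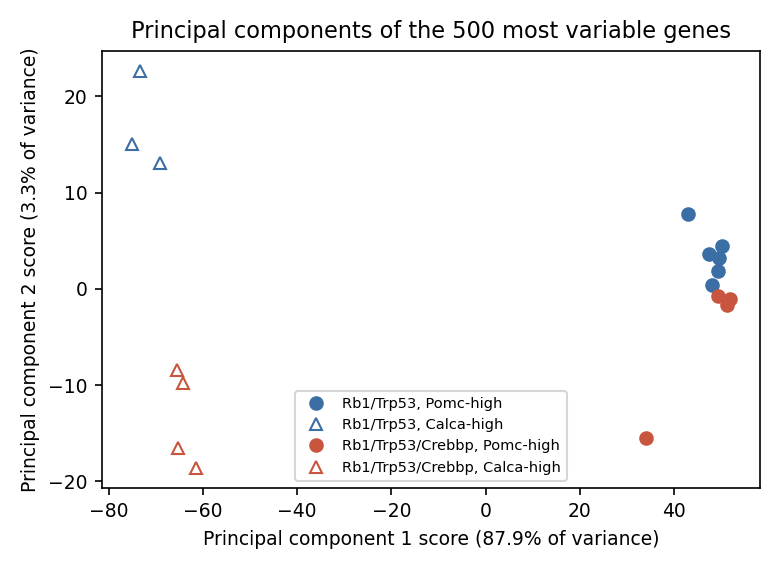
Scores of the 17 libraries on the first (87.9% of variance) and second (3.3%) principal component of log2 CPM, with Rb1/Trp53 in blue, Rb1/Trp53/Crebbp in red, filled circles for Pomc-high and open triangles for Calca-high libraries. The first component separates the circles from the triangles, and on the second all red points lie below all blue ones.

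Within the 10 Pomc-high libraries (6 Rb1/Trp53, 4 Rb1/Trp53/Crebbp), the tachykinin precursor gene Tac1 (3.99 ± 0.44), the growth factor gene Mdk (2.83 ± 0.30), Stmn2 (2.72 ± 0.48) and Cntn1 (2.11 ± 0.30) rose, with Cwc22 (4.40 ± 0.09) and Il1f9 (2.82 ± 0.22). The growth factor gene Bmp7 (-2.69 ± 0.45), the laminin gene Lama5 (-2.07 ± 0.21) and Wnt4 (-2.12 ± 0.31) fell. Of 21 genes of neuronal differentiation, 4 rose and 3 fell, and 7 rose and 3 fell when adjusted over the list alone (adjusted p = 0.80 with an estimated correlation). Of 13 posterior lobe pituicyte and astroglia genes 1 fell (median 1.33), and of 14 genes of neurons and oligodendrocytes 1 rose and 1 fell (median 0.74), also when adjusted over the lists alone (adjusted p = 0.944 and 0.971 with an estimated correlation). Of 29 genes of hypoxia and glycolysis, 8 fell, among them the hexokinase gene Hk2 (-1.04 ± 0.15) and Egln3 (-0.92 ± 0.14), and 10 fell when adjusted over the list alone (adjusted p = 0.791 with an estimated correlation). Of 24 genes of the unfolded protein response, 6 fell, among them Eif2ak3 (-0.56 ± 0.09), and 10 fell when adjusted over the list alone (adjusted p = 0.791 with an estimated correlation). Of 21 endothelial genes, 5 fell, among them Kdr (-1.39 ± 0.28), and 8 fell when adjusted over the list alone (adjusted p = 0.791 with an estimated correlation). Of 23 macrophage genes, 2 fell, also when adjusted over the list alone (median -1.001, camera adjusted p = 2.37e-04, adjusted p = 0.80 with an estimated correlation). Of 7 MHC class II genes (median -1.49, camera adjusted p = 0.0157) and 34 interferon response genes (median -0.53, camera adjusted p = 0.0127), 0 passed, also when adjusted over the lists alone (adjusted p = 0.80 and 0.944 with an estimated correlation). T8 of the Rb1/Trp53/Crebbp group stood apart from the other 3 of its genotype in this set: Pomc took 10.6% of its counts against 18.24% to 22.05%, and its score on the first component was 34.0 against 49.3 to 51.9. Its chi-square per degree of freedom against the 3 was 53.8 to 60.1, and 8.30 to 22.3 among them. In this subset, chosen after the sets had been seen, 1179 of 14010 genes changed, 442 higher and 737 lower, and 764 changed without Rb1/Trp53/Crebbp T7. Of 101 called genes named by the rule, 68 kept their call in every fit without 1 tumour. Cdh1 stood at 0.90 to 6.69 CPM, with a log2 fold change of -0.32 (adjusted p = 0.79).

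Within the 7 Calca-high libraries (3 Rb1/Trp53, 4 Rb1/Trp53/Crebbp), 18 of 36 lists passed camera, and 0 passed with an estimated correlation. Of 46 cell adhesion molecules, 29 rose, among them Cntn1 (4.40 ± 0.29), Pcdh10 (4.995 ± 0.41) and Pcdh17 (3.56 ± 0.32), 2 fell, and 32 rose and 2 fell when adjusted over the list alone (adjusted p = 0.302 with an estimated correlation). Of 54 ion channel genes, 28 rose, 4 fell and 22 did not pass, and 29 rose and 6 fell when adjusted over the list alone (adjusted p = 0.394 with an estimated correlation). Of 58 cell cycle genes, 39 rose, among them Ccne2 (1.33 ± 0.11) and Mcm6 (0.70 ± 0.07), and 48 rose when adjusted over the list alone (adjusted p = 0.43 with an estimated correlation). Of 52 epithelial genes, 24 fell, among them Cdh1 (-1.89 ± 0.15, adjusted p = 5.86e-04) and the claudin gene Cldn3 (-1.24 ± 0.11), 6 rose and 22 did not pass, and 27 fell and 7 rose when adjusted over the list alone (adjusted p = 0.454 with an estimated correlation). Of 46 ribosomal protein genes, 43 fell, among them Rps23 (-0.72 ± 0.09) and Rplp1 (-0.72 ± 0.10), and 44 fell when adjusted over the list alone (adjusted p = 0.454 with an estimated correlation). Of 35 oxidative phosphorylation genes, 20 fell, among them Cox6b1 (-0.63 ± 0.08), and 23 fell when adjusted over the list alone (adjusted p = 0.302 with an estimated correlation). The neuronal adhesion gene Astn1 rose (5.15 ± 0.41). Hoxd3 stood at 32.7, 3.51, 34.7 and 0.26 CPM in Rb1/Trp53/Crebbp T1 to T4 and at 0.04 to 0.23 CPM in the 3 others, and it lost its call without any of the 3 Rb1/Trp53 libraries (adjusted p = 0.0812, 0.0963 and 0.104). Of 18 acetyltransferase genes, 6 rose and 3 fell, and 7 rose and 3 fell when adjusted over the list alone (adjusted p = 0.645 with an estimated correlation). Ep300 (0.78 ± 0.09, adjusted p = 0.00118), Crebbp (0.60, adjusted p = 0.00723) and Ncoa2 (0.85 ± 0.11) were among those that rose. Of 163 called genes named by the rule, 136 kept their call in every fit without 1 tumour.

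Other features of the 7 Calca-high libraries went with the genotype. Of 22 endothelial genes, 12 fell, and 16 fell and 1 rose when adjusted over the list alone (median -0.75, adjusted p = 0.454 with an estimated correlation). Of 25 fibroblast and pericyte genes, 6 fell, and 3 fell when adjusted over the list alone (median -0.74, adjusted p = 0.645). Of 23 macrophage genes, 5 fell, also when adjusted over the list alone (median -0.53, adjusted p = 0.681). The fat cell gene Cfd stood at 11.1 to 91.6 CPM in the 3 Rb1/Trp53 libraries and at 0.07 to 2.52 CPM in the 4 others, and Car3 at 9.48 to 137 and 0.15 to 2.76 CPM. Tg, the thyroglobulin gene of thyroid follicular cells, stood at 16680, 6211 and 2012 CPM in the 3 Rb1/Trp53 libraries and at 1025 to 1397 CPM in the 4 others. Total counts were 20361712 to 28140755 in the 3 and 8328297 to 15490074 in the 4. In the Pomc-high set, Y-linked genes were expressed in 1 of 6 Rb1/Trp53 and 0 of 4 Rb1/Trp53/Crebbp libraries. In the Calca-high set they were expressed in all 3 Rb1/Trp53 libraries and in 1 of the 4 others. Y-linked expression was thus more frequent in Rb1/Trp53 over all 17 libraries as well as in the Calca-high ones. In this subset, also chosen after the sets had been seen, 5355 of 14797 genes changed, 2821 higher and 2534 lower, and with upper-quartile normalization 2514 were higher and 2879 lower. With the Y-linked genes as a covariate 625 genes changed. Under that covariate the log2 fold change of Cdh1 went from -1.89 to -1.64 and that of Ep300 from 0.78 to 0.73, both still past the threshold, and that of Crebbp from 0.60 to 0.41 (adjusted p = 0.152).

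The genotype effects in the 10 Pomc-high and the 7 Calca-high libraries, which share no tumour, overlapped in part. Of 13632 genes tested in both, 141 rose in both, against 84.5 for independent lists (one-sided Fisher exact p = 4.23e-11). Another 180 fell in both, against 117 (one-sided Fisher exact p = 2.81e-10). A further 126 went opposite ways, and the number expected for independent lists was not computed for these. With the Y-linked covariate 36 rose and 27 fell in both, but fewer genes were called in each set. The calls were then 311 higher and 649 lower in the Pomc-high libraries, and 462 higher and 163 lower in the Calca-high ones. The number expected for independent lists was not computed for these calls, so 36 and 27 cannot be set against 84.5 and 117. Genes are not independent replicates, so these p-values describe the overlap of the 2 tables. Across genes the log2 fold changes had Pearson r = 0.194 and Spearman rho = 0.137. Cwc22, Cntn1, Il1f9, Scn9a and Cend1 were among the genes that rose in both. The genotype effect differed between the sets for 3543 genes in an interaction test.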

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

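The interaction of genotype and set, the split of the libraries into sets, the test on Gh and Prl and the test on sex were chosen only after the result had been seen.

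The first pattern was the 7 libraries with Calca and without Pomc, which the labels place with the others as pituitary tumours. Tissue of a pituitary tumour with neighbouring anterior lobe cells was argued against by Gh and Prl, whose summed level reached 0.138 CPM at most in the 7 libraries and 10.6 to 13560 CPM in the 10 others; Gh had 0 counts in all 7, which allows up to 0.36 CPM in the shallowest by counting error. Tissue from the thyroid stayed open as a hypothesis, since 9 follicular genes summed to at least 7.26 times the highest of the 10 others in every one of the 7 libraries, with a median of 1397 CPM for Tg. Tissue from the lung also stayed open but barely, with a ratio of 1.02 over 10 lung genes, kept low by Hopx in the 10 others; Sftpc had a median of 39.3 CPM, Ager 59.9 CPM and Sftpb 24.7 CPM, Scgb1a1 1.24 CPM and Lamp3 0 CPM, and Hopx had a median of 3.44 CPM against 61.1 CPM in the 10 others. Genes of a list for thyroid C cells, drawn up after Calca had been seen, were also high in each of the 7 libraries, with Hhex at 210 to 469 CPM (1.83 CPM at most in the 10 others), Foxa1 at 97.1 to 150 CPM (1.71), Foxa2 at 88.9 to 165 CPM (0.82) and Calcb at 5.16 to 14.4 CPM (0.15), while Cckbr and Slc5a7 of that list reached 0.11 and 0.67 CPM. No test had been set for this list, and Foxa1, Foxa2 and Nkx2-1 are also genes of the lung. A tumour of Pomc-producing pituitary cells free of such neighbouring cells was argued against in the 7 libraries by Tbx19 and Pax7. They reached 0.36 and 0.21 CPM at most there, against at least 275 and 141 CPM in the 10 others. A pituitary tumour of another cell type, free of such neighbouring cells, was not excluded. The tests say nothing of how the tumours were dissected, and no biological explanation for the split was tested.

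The second pattern was the rise of Cwc22 in all 8 Rb1/Trp53/Crebbp libraries, which may come from DNA of another strain carried with the bred alleles. Of the 20 tested genes nearest Cwc22, 6 changed with the set as a term (30.0%, 95% exact binomial interval 11.9% to 54.3%) against 18.0% of other genes (one-sided Fisher exact p = 0.135), so a regional difference cannot be told apart from none. Around Crebbp, 4 of 35 genes changed (11.4%, 3.20% to 26.7%, one-sided Fisher exact p = 0.898); 50 had been asked for, and 10 tested genes lay on one side. This test left out 4930562C15Rik, which has 11 tested genes between it and Crebbp and was already known to rise (2.49 ± 0.17 with the set as a term, 2.35 ± 0.23 in the Pomc-high and 2.72 ± 0.18 in the Calca-high libraries). The share around Crebbp met the bound written beforehand against a strain effect, but the interval reaches well past 18.0%, so it was left open, a rule that was changed after the result was seen. Extra copies of Cwc22 in 1 genotype could not be tested on these counts, and an effect of the Crebbp genotype on Cwc22 itself remains open.

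The third pattern was the 5355 genes that changed in the 7 Calca-high libraries. A difference in library size as the whole cause was argued against by thinning every library to 8328297 counts, which left 4818 changed genes. Sex cannot be told apart from genotype here: T1 of the Rb1/Trp53/Crebbp group, the single library of that group with Y-linked expression, lay on the side of its own genotype for 84.4% of 4339 autosomal genes called without it, but 1 library excludes nothing, a reading adopted after the result was seen. With the Y-linked covariate 625 genes changed. Of 4 libraries with Y-linked expression 3 were Rb1/Trp53, so the covariate overlaps the genotype, and the cause of the lower count was not tested. A part played by sex, by the share of reads assigned to no feature, or by fat or follicular tissue in the samples stays open. A part played by the Crebbp genotype also stays open, as a hypothesis.

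Chance was argued against for the gene counts by random splits. The 554 genes over all 17 tumours were reached by 1 of 100 random splits, the real one, and the highest other split gave 19; for genes changed at least 2-fold it was 182 against 7, also 1 of 100. With the set as a term 1 of 100 splits reached 2575 (highest other 129), and in the Pomc-high libraries 1 of 100 reached 1179 (highest other 4). In the Calca-high libraries 1 of 35 reached 5355 (highest other 7). Those 35 are all the possible splits, so the smallest p is 0.0286 and chance is not excluded there. Nor could chance be excluded for the number of gene lists past camera. Over all tumours 77 of 100 splits gave the 10 lists or more (highest other 19), and 50 of 100 gave the 13 with the set as a term (highest other 22). In the Pomc-high libraries 61 of 100 gave the 14 (highest other 28), and in the Calca-high ones 2 of 35 gave the 18 (highest other 18). For single lists chance was argued against by the exact permutation test, adjusted over the lists. Over all tumours this held for neuronal differentiation (0.00296) and the unfolded protein response (0.0207), and with the set as a term for 10 of 36 lists. With an estimated correlation neither of the 2 lists passed camera (adjusted p = 0.161 for both), and 0 lists passed it with the set as a term. An unequal mix of the sets as the cause of the 554 genes was argued against by the fit with the set as a term, which kept 551 of them. That fit gave 4.65 times as many genes. The ratio does not decide, because a term that takes up spread between libraries can raise the count either way.

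In the interaction test the genotype effect differed between the sets for 3543 genes. As many were reached by 2 of 100 splits within the sets, the real one included. The other one (4445 genes) kept every label of the Calca-high libraries and exchanged 8 labels of the Pomc-high ones. That split kept the genotype effect in the Calca-high set and largely reversed it in the Pomc-high set. Splits that mix the genotypes in both sets weaken both effects. The splits therefore cannot tell whether the effects were equal. As effects in Pomc-high minus Calca-high libraries on the log2 scale, the genotype effect was smaller or lower for genes that included Onecut2 (-3.14), Cdh6 (-2.30), Cntn1 (-2.29), Rab11fip4 (-2.19), Nlgn3 (-1.45), Crebbp (-1.07) and Ep300 (-0.67). It was higher for Efna1 (0.81), Pcsk2 (0.83), Glrb (1.04), Slc18a1 (1.13), Gstm2 (1.35), Cpa5 (1.57), Reep6 (1.75) and Fabp4 (2.53).

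In 5 of 170 groups of values a single library lay far from the others of its genotype by Dixon's test, where chance gives about 1 in 20. On the log2 CPM scale, Vsnl1 stood at 6.14 in Rb1/Trp53/Crebbp T8 (nearest 2.24) and Neurod4 at 2.10 in Rb1/Trp53/Crebbp T6 (nearest 1.64). Btg2 stood at 8.45 in Rb1/Trp53 T6 (nearest 7.87) and at 8.06 in Rb1/Trp53/Crebbp T6 (nearest 7.16), and Ptprb at 1.73 in Rb1/Trp53/Crebbp T7 (nearest 2.57).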

How the results depend on the processing

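The alternatives with the set as a term or with 1 set alone, and all alternatives of those fits, were chosen after seeing the data. The 554 genes became 1397 with DESeq2 (369 at least 2-fold), 7467 with voom quality weights (2205), 1527 with the Y-linked covariate (443), 928, 1134 and 2583 with the somatotroph, macrophage and fibroblast covariates (275, 416 and 659), 2662 with 1 surrogate variable (585), 2575 with the set as a term (575), 1179 in the Pomc-high (368) and 5355 in the Calca-high libraries (1725); the cause was not tested. The count stayed within 1.5 times under the size factors, upper quartile, both filters and limma-voom, at 469 to 575. The share of higher genes was 46.9%, and 57.8% with the macrophage covariate. Leaving out each tumour gave 284 to 1031 genes (112 to 269 at least 2-fold, with 117, 113 and 112 without Rb1/Trp53 T7 and Rb1/Trp53/Crebbp T3 and T4), 764 to 1215 in the Pomc-high and 3591 to 5243 in the Calca-high libraries. With the Y-linked covariate 1282 genes changed with the set as a term and 625 in the Calca-high libraries, and DESeq2 gave 1917 in the Pomc-high ones. The 10 lists became 0 with an estimated correlation, 4 with fry, 2 with exact permutation and 18 in the Calca-high libraries; with an estimated correlation the counts were 0 with the set as a term and in both sets. With the set as a term fry and exact permutation each gave 10 lists, in the Pomc-high libraries fry gave 1 and exact permutation 0, and in the Calca-high ones fry gave 18 and exact permutation 0, where its smallest p is 0.0286. In the Pomc-high libraries alone chromatin remodelling and ribosomal proteins turned direction (adjusted p = 0.783 and 0.652). There, acetyltransferases turned with fry (0.985) and exact permutation (0.845), ion channels with fry (0.985) and the stricter filter (0.984), and chromatin remodelling and ribosomal proteins with the replicate block (0.673 and 0.426). Leaving out 1 tumour moved these 4 lists between 0.638 and 0.998, 0.304 and 0.991, 0.277 and 0.945, and 0.0897 and 0.969. Genes risen and fallen in both sets numbered 255 and 294 with DESeq2 and 36 and 27 with the Y-linked covariate, and 98 to 163 and 121 to 186 without 1 tumour. The 3543 genes whose effect differed between the sets stayed within 1.5 times in every setting run. Of 66 called named genes, 33 lost the call with the replicate block, 23 with limma-voom, 11 without the low-count filter, 12 in the Calca-high and 27 of 63 in the Pomc-high libraries and 2 to 25 without 1 tumour, and none turned direction in any alternative.

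Some values turned sign, and with quality weights Calca (adjusted p = 0.00955) and Cdh1 (0.041) passed the threshold in the turned direction. Crebbp was 0.011 with voom, 0.0887 with quality weights, 0.0267 and 0.0514 with the Y-linked and macrophage covariates and 0.60 in the Calca-high libraries. Calca was 0.48 with voom, 6.003 with quality weights, 6.76, 4.27 and 2.06 with the Y-linked, macrophage and fibroblast covariates and 1.05 with the surrogate variable. Cdh1 was 3.16 with quality weights, then 2.54, 1.25, 0.547 and 0.0347 with the Y-linked, macrophage and fibroblast covariates and the surrogate variable. These fits take in both sets, and Cdh1 stood at 61.8 to 297 CPM in the Calca-high and 0.90 to 6.69 CPM in the Pomc-high libraries. Within the Calca-high libraries the fall of Cdh1 stayed past the threshold in every fit without 1 tumour. Syp was -0.17 with quality weights, -0.0247 with the Y-linked covariate and -0.15 in the Calca-high libraries. Gh was 0.0278 and Prl 0.27 with the somatotroph covariate, and Pomc was 0.41 in the Calca-high libraries, -0.60 there with voom. Leaving out 1 tumour moved Crebbp from -0.1002 to 0.127, Gh from -3.043 to 0.129, Syp from -0.0118 to 0.12, Gh, Cdh1 and Calca in the Pomc-high libraries from -2.379 to 0.472, -1.262 to 0.0443 and -1.736 to 0.104, and Pomc in the Calca-high ones from -1.843 to 1.702; the cause was not tested.

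Both genotypes have tumours numbered T1 to T8, but nothing in the labels says that a number pairs them. Same-number correlations ran from -0.652 to 0.77, with 7 of 8 numbers in the same set, and from -0.163 to 0.194 with the mean of each genotype in each set removed, and 3 of 8 tumours correlated best with their own number. With the replicate block 432 genes changed over all tumours, 626 with the set as a term, 349 in the Pomc-high and 2713 in the Calca-high libraries, 33 rose and 55 fell in both sets, and Crebbp was 0.0577. Depth limits low genes: the shallowest library held 8328297 counts.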

Other observations

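All tests within the sets of libraries were chosen only after the result had been seen. In the Calca-high libraries, where 36.2% of all tested genes changed, further genes and lists were looked at. Nkx2-2, a transcription factor of endocrine cells, stood at 9.42 to 21.7 CPM in the 3 Rb1/Trp53 and 0.6 to 1.56 CPM in the 4 Rb1/Trp53/Crebbp libraries, and Gcg, the glucagon precursor gene, at 0 to 0.04 and 1.44 to 12.8 CPM. Of 30 genes of hypoxia and glycolysis, 8 rose, among them the carbonic anhydrase gene Car9 (3.55 ± 0.38), and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (adjusted p = 0.645 with an estimated correlation), while 8 of 29 fell in the Pomc-high libraries. Of 53 axon guidance genes, 17 rose, among them Plxnc1 (2.08 ± 0.17) and Efnb2 (1.99 ± 0.19), and 5 fell, and 21 rose and 5 fell when adjusted over the list alone (adjusted p = 0.302 with an estimated correlation). Of 25 sterol and lipid synthesis genes, 9 rose, among them Acly (1.13 ± 0.21), and 2 fell, also when adjusted over the list alone (adjusted p = 0.689 with an estimated correlation).

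Of 20 melanotroph and corticotroph genes, 3 fell within the Pomc-high libraries, Pam (-0.66 ± 0.10), the dopamine receptor gene Drd2 (-0.72 ± 0.16) and Pcsk2 (-0.79 ± 0.19), and 17 did not pass. Adjusted over the list alone, 1 rose and 6 fell (adjusted p = 0.791 with an estimated correlation). The granin genes Chgb (-0.65 ± 0.13) and Vgf (-0.81 ± 0.17) also fell there, and Uchl1 rose (1.36 ± 0.21). Of 41 neuroendocrine and secretory granule genes in these libraries, 2 rose, 4 fell and 35 did not pass. Adjusted over that list alone, 6 rose and 7 fell (median 0.03, adjusted p = 0.991 by camera with an estimated correlation).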
